A study of Arabidopsis thaliana with 8 samples.

How the data were processed

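Ribosome footprints and mRNA of Arabidopsis thaliana were measured under dark and blue-light conditions, in 8 libraries that form 4 groups of 2 replicates. Per the labels, footprints were made by RNase I digestion and pelleting of ribosomes, followed by linker ligation, removal of ribosomal RNA, circularisation and amplification, and mRNA libraries were made with a TruSeq kit. The labels give no tissue, plant age, light intensity or duration.

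The deposited files hold whole-number counts of reads per transcript model, with no normalization, and 1 file per library. The authors' processing notes name CASAVA 1.8, Bowtie2 2.1.0, TopHat2 2.0.9 and genome build TAIR10, without the role of each, and do not name the counting tool. Each file lists 41671 transcript models of 33602 loci. Another column, identical in all files, resembles the length of the counted coding region in codons and was used to choose 1 model per locus and for the length alternative below. The 6285 models without a length had 0 counts in all libraries, and 27416 loci remained. Models of the same locus shared reads, so counts were not summed over them, and the longest model was taken at the 5885 loci with more than 1. The duplicated chloroplast genes ATCG00860 and ATCG01280 held 43540 counts each in blue mRNA replicate 1, so reads that match several places appear to be counted at each, and near-identical genes can share reads. Symbols came from a reference table for TAIR10.1 joined by locus tag, which matched 26719 loci and gave 10376 a symbol. No coordinates are given, since that table and the counts refer to different releases of the build.

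Groups were taken from the labels, and 3 tests were fixed before the data were examined, as were the 16 gene lists, the rule for naming genes and most of the alternatives. Blue light was compared with darkness in the 4 mRNA libraries, in the 4 footprint libraries, and, as the interaction of assay and light over all 8 libraries, in the ratio of footprints to mRNA (translational efficiency). Each test used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr at a minimum count of 10 and the quasi-likelihood F-test, two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. For efficiency, a gene had to pass the filter in both assays, and scaling used those genes over all 8 libraries. The spread was estimated separately in the mRNA and footprint tests. In the efficiency test 1 spread per gene was shared by both assays. Its common dispersion was 0.0044, against 0.052 in the mRNA test and 0.0023 in the footprint test. Fold changes are fitted log2 values, and CPM are scaled by TMM library size and given as mean and SD. The SE of a fold change is its absolute value divided by the square root of the F statistic. It approximates a standard error and can lie below counting error where a group has few counts. Efficiency levels per library used a pseudocount of 0.5 CPM.

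Gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 between genes, two-sided, adjusted over the lists within each test, for lists with at least 5 tested members. An estimated correlation was the alternative. It raised p even where the estimate was below 0.01. The photoprotection list in mRNA, with an estimate of -0.11, went from an adjusted camera p of 1.43e-41 to 0.0781. Calls lost under this alternative therefore cannot be put down to correlated genes alone. Whether it could have called any list with 2 replicates per group was not tested, so it does not decide whether a list call holds. The lists cover light signalling, antenna, photosystem and Rubisco, photoprotection, tetrapyrrole, flavonoid, clock, auxin and elongation, starvation, ribosomal protein, conserved-peptide uORF, heat shock, root and seed genes, and the chloroplast- and mitochondrion-encoded genes by locus prefix. They were written from general knowledge and are not the study's own. List members that could not be tested were left out of the counts.

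The genes named in each test were the 10 with the largest rise and the 10 with the largest fall among called nuclear loci with a symbol, where both blue-light libraries lay beyond both dark libraries and the mean count was at least 100. Up to 4 members of each list with the largest change followed, and HY5, TT4, ELIP1, CAB2, PORA, PIF4, SAC51 and GBF6 were always included. Named beyond this rule, and chosen after their values were seen, were members of lists in which 5 or fewer genes were called, the members of the light signalling list called in efficiency, the genes with opposite calls in mRNA and footprints, 3 loci that took a large share of mRNA counts, and the examples in the other observations.

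The alternatives chosen beforehand were the DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a stricter filter of at least 10 CPM, nuclear genes only, the replicate number as a block, for efficiency also a block within each condition and scaling within each assay, and leaving out each library in turn. Chosen after the data were seen were the lowest-numbered transcript model and the removal of a trend on coding length. Footprints thinned to the nuclear counts of the shallowest mRNA library were also chosen then. Leaving out a library leaves a group of 1, whose spread is assumed to be that of the other group or groups in the model. The count filter was rerun each time, and more genes then entered. Without an mRNA library 10104 to 10372 mRNAs were tested against 7822, and 7578 to 7821 genes for efficiency against 6169. List medians and adjusted p without a library are therefore over other sets of genes.

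Depth was 688630 to 847469 counts per mRNA library and 2888624 to 4919808 per footprint library. At least 10 counts were present at 5723 to 8205 loci per mRNA library and at 15133 to 16237 per footprint library. Deviations between replicates exceeded counting noise in all 4 groups, with a chi-square per degree of freedom of 3.75 in dark mRNA, 2.76 in blue mRNA, 1.42 in dark footprints and 1.61 in blue footprints, over loci with a summed count of at least 20. Floors cover counting error only, since reads carried no molecular identifiers as far as the labels state.

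The tests were also tested on simulated data with the depth of these libraries and the spread per gene fitted in each test. For efficiency that spread was shared by both assays, so simulated mRNA varied less than the real mRNA. The efficiency values that follow can therefore be too favourable. At a log2 change of 1, 13% of changed genes were recovered for mRNA, 64% for footprints and 29% for efficiency, and at a change of 2, 66%, 95% and 72%. False calls made up 2.47%, 3.05% and 7.34% of all calls. Each simulation changed 100 genes by 1 and 100 by 2, with as many raised as lowered. In the data 5975 of 15788 footprints were called, so these rates need not hold for the data. Of 20 random lists per test, 0, 0 and 2 had a camera p under 0.05.

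A planned comparison of genes with and without an upstream ATG was not run, since no annotation of 5′ leaders was among the reference data used here, and alternatives meant for normalized values did not apply to counts. Figures were drawn with matplotlib 3.10.9 and tables were read with pandas 2.3.3.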

Results

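Ribosome footprints and mRNA of Arabidopsis thaliana were compared between darkness and blue light. Ribosome profiling sequences the stretches of mRNA that ribosomes protect from RNase I, so the footprint count of a gene reports the ribosomes on its coding sequence, and the ratio of footprints to mRNA gives its translational efficiency. The title of the series frames the question around upstream open reading frames (uORFs), short reading frames in the leader of an mRNA that can lower translation of the main coding sequence, and around transcripts that start downstream of them in blue light. The counts are given per gene model, so start sites of transcripts were not analysed here, and the comparisons below concern mRNA level, footprint level and efficiency per gene.

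Dark mRNA, blue-light mRNA, dark footprints and blue-light footprints were each represented by 2 libraries. The mRNA libraries held 688630 to 847469 counts over 27416 loci, and the footprint libraries held 2888624 to 4919808. Chloroplast-encoded genes took 45.4% ± 0.24 of the mRNA counts in the dark and 47.2% ± 2.14 in blue light (SD, n = 2), but 0.898% ± 0.094 and 0.793% ± 0.078 of the footprint counts. Another 3 loci without a symbol, AT1G40104, AT2G08986 and AT2G07981, took 16.6% ± 3.46 of the dark and 13.4% ± 2.25 of the blue-light mRNA counts. They had 0 footprint counts, which allows a share of up to 1.04e-04% in the shallowest footprint library (counting error only). Nuclear genes, these 3 loci included, therefore rested on 331867 to 436399 counts per mRNA library. Replicate footprint libraries had Spearman correlations across loci of 0.986 in the dark and 0.989 in blue light, and replicate mRNA libraries 0.777 and 0.735. The correlation of any mRNA library with any footprint library was between 0.167 and 0.271 across loci, which are not independent replicates. The median standard error of a log2 fold change was 0.51 for mRNA, 0.19 for footprints and 0.48 for efficiency. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries only, whether technical or biological.

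The first comparison asked which mRNAs differed between blue light and darkness. Single genes were ranked among called nuclear loci with a symbol and a mean of at least 100 counts. The 10 largest rises were in genes of the photosynthetic apparatus, chlorophyll synthesis and light protection. ELIP1 (AT3G22840), an early light-induced protein of the thylakoid, rose from 12.9 ± 5.0 to 997 ± 24 CPM (library-scaled counts, mean ± SD, n = 2), a log2 fold change of 6.26 ± 0.32 (SE, adjusted p = 3.89e-14, edgeR quasi-likelihood test), and its relative ELIP2 rose by 5.34 ± 0.26. CAB2 (AT1G29920, listed as LHCB1.1), an antenna protein of photosystem II, rose from 63.5 ± 6.8 to 2745 ± 167 CPM, with a log2 fold change of 5.43 ± 0.25 (adjusted p = 6.73e-15). GUN5 (AT5G13630), the large subunit of the magnesium chelatase that opens the chlorophyll branch, rose by 4.25 ± 0.25, and NPQ4 (AT1G44575), the PsbS protein of energy quenching, by 3.71 ± 0.24 (adjusted p = 8.89e-13 and 4.96e-12). Under that limit the falls were led by GATA4 (AT3G60530), a transcription factor, at -3.69 ± 0.35, SAG20 (AT3G10985), named for senescence, at -2.88 ± 0.32, and XTH15 (AT4G14130), a xyloglucan endotransglucosylase of the cell wall, at -2.70 ± 0.34. J11 (AT4G36040) followed at -2.31 ± 0.28 and AT7SL-1 (AT4G02970), the RNA of the signal recognition particle, at -1.89 ± 0.23. ADC2 (AT4G34710), an arginine decarboxylase of polyamine synthesis, fell by 1.71 ± 0.26, ST2A (AT5G07010) by 1.68 ± 0.28 and DIN10 (AT5G20250), a dark-inducible gene, by 1.64 ± 0.30. BRI1 (AT4G39400), the brassinosteroid receptor, at -1.56 ± 0.28, and SAMDC (AT3G02470), an S-adenosylmethionine decarboxylase, at -1.42 ± 0.27 also passed, but not without blue mRNA replicate 1 (BRI1, adjusted p = 0.0908) or replicate 2 (SAMDC, adjusted p = 0.0820).

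Among the gene lists, 17 of the 18 light-harvesting antenna genes rose in mRNA (18 when adjusted over the list alone), with a median log2 fold change of 3.05. LHB1B1, LHCB2.2, LHB1B2, LHCB2.3 and LHCB2.1 rose by 5.11, 4.15, 3.94, 3.90 and 3.73. The members of the LHCB1 and LHCB2 families are near-identical and can share reads, so their single values are uncertain. Of 20 tested photosystem subunits and Rubisco genes encoded in the nucleus, 18 rose (the same number adjusted over the list alone), with a median of 1.97. RBCS1B (AT5G38430), a small subunit of Rubisco that also has close copies, rose by 2.70 ± 0.21 and PSAK (AT1G30380) by 2.81 ± 0.29. Photoprotection genes rose in 6 of 8 cases (7 adjusted over the list alone) and genes of tetrapyrrole and chlorophyll synthesis in 7 of 12 (7 adjusted over the list alone), the latter including HEMA1 (AT1G58290), which starts the pathway, at 3.47 ± 0.32. In phenylpropanoid and flavonoid synthesis 3 of 10 rose (7 adjusted over the list alone), among them TT4 (AT5G13930), chalcone synthase, at 3.76 ± 0.43, C4H (AT2G30490) at 1.62 ± 0.31, and TT5, which was counted 1 time in each dark mRNA library and 19 and 15 times in blue light and lost its call without either blue library (adjusted p = 0.414 and 0.219). Of 13 dark and sugar starvation genes 5 fell and none rose (7 adjusted over the list alone): DYL1 (AT1G28330) at -3.84 ± 0.56, AT3G15450 at -2.49 ± 0.32, SEN1 (AT4G35770) at -2.16 ± 0.35, ASN1 and DIN10. These 6 lists were called by camera with the preset correlation of 0.01, at adjusted p from 3.27e-125 for the antenna to 2.66e-07 for the flavonoid list. With an estimated correlation no list was called, and the adjusted p became 0.0781 for the antenna, photoprotection and tetrapyrrole lists, 0.142 for the photosystem list, 0.123 for the flavonoid list and 0.285 for the starvation list.

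Other lists moved less in mRNA. Of 9 conserved-peptide uORF genes, whose leaders encode a conserved short peptide, SAMDC fell (3 adjusted over the list alone), and the list had a median of -0.94 (adjusted p = 0.0185, and 0.285 with an estimated correlation). Without blue mRNA replicate 2 or dark mRNA replicate 2 that call was lost, at medians of -0.34 and -0.38 and adjusted p = 0.207 and 0.0665. In the heat shock and acute stress list HSP70 (AT3G12580) and HSP90.1 (AT5G52640) rose by 1.90 ± 0.36 and 1.8 ± 0.35 among 9 genes (2 adjusted over the list alone, list adjusted p = 0.0416, and 0.285 with an estimated correlation), a list call lost without dark or blue mRNA replicate 1 (adjusted p = 0.0915 and 0.0522). Among 17 photoreceptor and light signalling genes RUP2 (AT5G23730) and SIGE (AT5G24120) rose and BBX21 (AT1G75540) fell by 2.36 ± 0.37 (2 and 1 adjusted over the list alone, list adjusted p = 0.883). RUP2 lost its call without blue mRNA replicate 1 and SIGE without replicate 2 (adjusted p = 0.143 and 0.119). None of 5 circadian clock genes, 14 cytosolic ribosomal protein genes, 6 root markers or 111 mitochondrion-encoded genes passed in edgeR, where 0, 3, 1 and 6 of them had an unadjusted p under 0.05, and 1 root marker fell when adjusted over the list alone. In the auxin response and cell elongation list 1 of 9 genes, XTH15, fell (2 adjusted over the list alone, list adjusted p = 0.0669), and in the seed storage and oil body list ICL (AT3G21720), isocitrate lyase, rose by 1.32 ± 0.20 as 1 of 5 (1 adjusted over the list alone, list adjusted p = 0.420). Of 87 chloroplast-encoded genes 1, ATCG00220, rose (0 adjusted over the list alone, and its call was lost without dark or blue mRNA replicate 2, at adjusted p = 0.207 and 0.853), with a median of 0.24 (list adjusted p = 9.12e-05, and 0.668 with an estimated correlation), and the list call was lost without blue mRNA replicate 2 (adjusted p = 0.0926). The median was 0.15 without dark mRNA replicate 2 and 0.36 without blue mRNA replicate 1. The mitochondrion-encoded list had a median of 0.20 (adjusted p = 0.0470, and 0.595 with an estimated correlation), which was lost without dark mRNA replicate 1 or 2 or blue mRNA replicate 2 (adjusted p = 0.0539, 0.0611 and 0.437) and with the trend on coding length removed (0.777). Its median was 0.31 without blue mRNA replicate 1 and 0.12 without blue mRNA replicate 2. The camera direction opposed the sign of the median in the light signalling, clock and seed lists.

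PORA mRNA had a value of 0.33 ± 0.22 (0.031 without dark replicate 1 and 0.62 without dark replicate 2) and SAC51 mRNA -0.53 ± 0.84 (adjusted p = 0.616 and 0.893), and HY5, PIF4 and GBF6 had too few mRNA counts to be tested in mRNA or efficiency. In all, 305 of 7822 tested mRNAs changed, 223 upward and 82 downward (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). The fall count moved to 128 without dark mRNA replicate 1, to 49 without dark replicate 2 and to 52 without blue replicate 2. On simulated counts of this depth and spread the test recovered 13% of genes changed by 1 log2 unit and 66% of those changed by 2, so a gene not passing was not shown to be unchanged.

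The second comparison asked the same of ribosome footprints. CGA1 (AT4G26150), a GATA factor of chloroplast development, was counted 1 and 3 times in the dark libraries and 550 and 439 times in blue light, with a fitted log2 fold change of 7.58 ± 0.24 (edgeR adjusted p = 1.67e-20). Its value was 7.10 without dark footprint replicate 1 and 8.45 without dark footprint replicate 2, beyond that SE. The SE of other genes below with few dark counts can likewise be too small. THI2.2 (AT5G36910), a thionin, rose by 7.0 ± 0.21, and F3H (AT3G51240), flavanone 3-hydroxylase, rose from 2.77 ± 0.19 to 186 ± 0.94 CPM, a change of 6.06 ± 0.17 (adjusted p = 5.54e-22). BBX32 (AT3G21150), a B-box protein, had 3 counts in each dark library and a fitted change of 6.20 ± 0.26. ELIP1 and ELIP2 rose by 6.05 ± 0.10 and 5.84 ± 0.10, PRR9 (AT2G46790), a pseudo-response regulator of the clock, by 5.50 ± 0.27, and RUP2 (AT5G23730), a repressor of photomorphogenesis by ultraviolet-B light, by 5.41 ± 0.25. SIGE (AT5G24120, listed as SIG5), a sigma factor of the chloroplast RNA polymerase, rose by 5.36 ± 0.15 and STH (AT2G31380) by 5.10 ± 0.17. Among falls under the same limit, GRF7 (AT5G53660), a growth-regulating factor, came first at -4.31 ± 0.16 (adjusted p = 2.60e-19). XTH15 fell from 3877 ± 80 to 362 ± 1.2 CPM, a change of -3.42 ± 0.07 (adjusted p = 8.06e-25), followed by DYL1 at -3.26 ± 0.08 and SEN1 at -3.19 ± 0.08. SNRK2.5 (AT5G63650) stood at -3.19 ± 0.10, and HB-2 (AT4G16780, listed as ATHB2), a homeodomain factor of shade avoidance, at -3.13 ± 0.17. HB52 (AT5G53980), EDF3 (AT3G25730), ST2A and BT2 (AT3G48360) stood at -3.11 ± 0.15, -2.93 ± 0.18, -2.92 ± 0.10 and -2.83 ± 0.11.

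Of the nuclear lists, those for light signalling, the clock, flavonoids and photosynthesis were called higher in footprints at the preset correlation, and none of them at the estimated correlation. The same held for the heat shock list, which is given further below. All 18 antenna genes, all 23 photosystem and Rubisco genes, 10 of 11 photoprotection genes and 13 of 14 flavonoid genes rose, with medians of 2.60, 0.81, 2.50 and 3.95. TT4 rose from 10.5 ± 2.0 to 282 ± 6.2 CPM, a log2 fold change of 4.75 ± 0.13, and UGT78D2 (AT5G17050) by 4.98 ± 0.16. Of 17 tetrapyrrole genes 14 rose and 2 fell, the latter PORA (AT5G54190) at -0.55 ± 0.06 and PORB (AT4G27440) at -0.51 ± 0.06, both protochlorophyllide oxidoreductases. In the light signalling list 19 of 29 genes rose and 7 fell. HY5 (AT5G11260), a bZIP factor of photomorphogenesis, rose from 7.0 ± 2.1 to 94.2 ± 4.0 CPM, a change of 3.73 ± 0.17, SPA1 (AT2G46340) by 3.54 ± 0.12, PHOT2 (AT5G58140), a blue-light receptor, by 2.06 ± 0.10 and PIF4 (AT2G43010) by 0.97 ± 0.18, whereas PHYA (AT1G09570) and PHOT1 (AT3G45780) fell by 0.62 ± 0.07 and 0.75 ± 0.07. Clock genes rose in 14 of 17 cases, with CCA1 (AT2G46830) at 2.61 ± 0.11. The adjusted camera p of these 7 lists was between 3.25e-122 for the antenna and 4.21e-10 for light signalling, and with an estimated correlation 0.0682 for the antenna, photoprotection, tetrapyrrole and clock lists, 0.0717 for flavonoid synthesis and light signalling and 0.104 for the photosystem list.

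Lists for growth and starvation fell. Of 26 auxin response and elongation genes 16 fell and 2, EXPA1 and EXPA4, rose (18 and 2 adjusted over the list alone), with PIL1 (AT2G46970) at -3.44 ± 0.21 and IAA29 (AT4G32280) at -2.69 ± 0.27. The list had adjusted p = 1.18e-08, and 0.212 with an estimated correlation. Of 15 dark and sugar starvation genes 14 fell and 1, TPS5, rose, with ASN1 (AT3G47340), asparagine synthetase, at -2.32 ± 0.07 (list adjusted p = 3.20e-33, and 0.0717 with an estimated correlation). Root and root hair markers fell in 6 of 9 cases (7 adjusted over the list alone) and 1, SCR, rose, with a median of -0.63 (list adjusted p = 0.0338, and 0.212 with an estimated correlation). In the heat shock list 7 of 12 rose and 2, WRKY40 and TCH3, fell, with HSP70 at 2.50 ± 0.08 and HSP101 (AT1G74310) at 2.16 ± 0.16 (list adjusted p = 2.46e-04, and 0.212 with an estimated correlation). Among 18 conserved-peptide uORF genes 6 rose and 4, bZIP1, bZIP2, bZIP44 and XPL1, fell (6 and 5 adjusted over the list alone, list adjusted p = 0.0677). VTC2 (AT4G26850), the GDP-L-galactose phosphorylase that controls ascorbate synthesis, rose by 4.56 ± 0.09, while SAC51 (AT5G64340) had a value of 0.07 ± 0.31 and GBF6 (AT4G34590, listed as BZIP11) had too few counts to be tested. Ribosomal protein genes rose in 12 of 31 cases with a median of 0.16 (0.090 without dark footprint replicate 2, list adjusted p = 0.271), and of 8 seed storage genes ICL and PCK1 rose and SESA3 and MLS fell (list adjusted p = 0.150, with a camera direction opposed to the sign of the median). Chloroplast-encoded genes fell in 33 of 77 cases and rose in 2, ATCG00020 at 1.88 ± 0.10 and ATCG00490 at 0.41 ± 0.07, with a median of -0.39 (list adjusted p = 0.00423, and 0.564 with an estimated correlation), which was -0.26 without blue footprint replicate 2 and -0.24 without dark footprint replicate 2. Of 25 mitochondrion-encoded genes ATMG00220 and ATMG00370 fell and ATMG00280 rose (list adjusted p = 0.225), and ATMG00370 lost its call without each footprint library in turn (adjusted p from 0.0697 to 0.148). Counts adjusted over the list alone equalled those over all genes in every footprint list but the auxin, root and uORF lists.

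Footprints of 5975 of 15788 tested genes changed, 3304 upward and 2671 downward, of which 1436 and 675 by at least 2-fold (edgeR quasi-likelihood F-test, adjusted p under 0.05). The DESeq2 Wald test called 3264 genes, 2078 upward and 1186 downward. Thinning each footprint library to the 331867 nuclear counts of the shallowest mRNA library left 1423 calls among 6074 tested genes, 893 upward and 530 downward. The balance of directions thus depended on the processing.

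**Figure D1:**
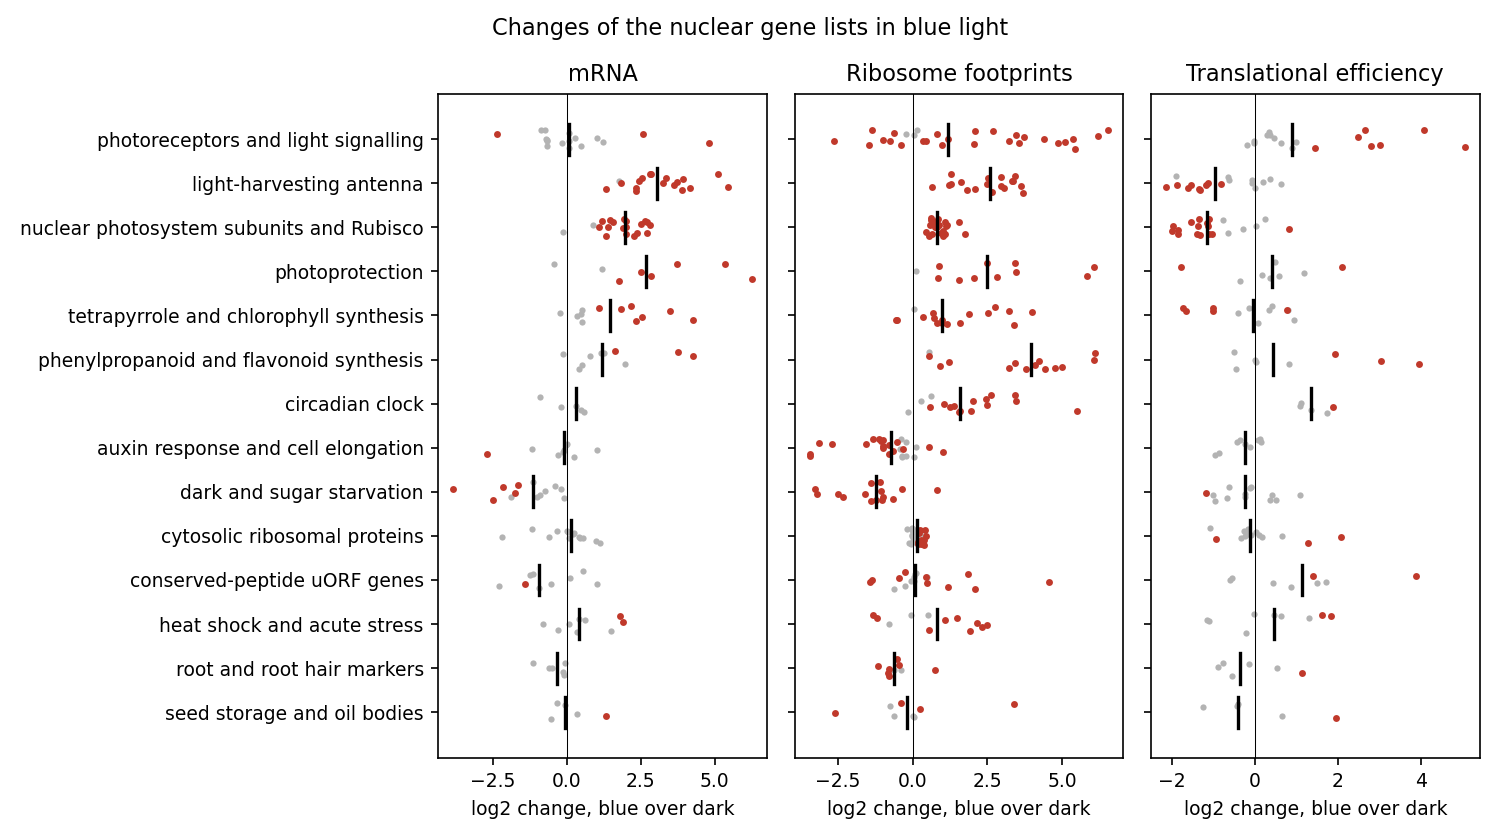
Log2 changes in blue light over darkness for the members of the 14 nuclear gene lists, for mRNA (left), ribosome footprints (middle) and translational efficiency (right). Each point is a gene, red where its adjusted p was under 0.05 and grey otherwise, and the black bar is the list median, which for the photosystem list was 1.97 in mRNA, 0.81 in footprints and -1.15 in efficiency.

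The third comparison tested whether footprints per mRNA differed, as the interaction of assay and light in 1 model over all 8 libraries. That model shares 1 spread per gene between the noisier mRNA and the footprints, so its SE and p-values can be too small. In EBF1 and ADC2 the SE was 0.33 and 0.21 for efficiency, but 0.35 and 0.26 for mRNA alone. Under the same limit on symbol and mean count the largest rise of efficiency was that of EBF1 (AT2G25490), an F-box protein that removes the ethylene factor EIN3, by 4.50 ± 0.33 log2 units (edgeR adjusted p = 9.87e-10). Its mRNA fell from 87.0 ± 3.1 to 34.2 ± 5.4 CPM while its footprints rose from 12 ± 3.3 to 117 ± 15 CPM. SPA1, a partner of the ubiquitin ligase COP1, rose by 4.07 ± 0.45 and VTC2 by 3.87 ± 0.34 (adjusted p = 8.98e-07 and 2.34e-08). VTC2 mRNA was at 41.3 ± 4.7 CPM in the dark and 61.4 ± 11 in blue light, which did not pass (adjusted p = 0.553), against 43.8 ± 4.8 and 1039 ± 18 CPM of footprints. MTN1 (AT4G38800), a methylthioadenosine nucleosidase, rose by 3.90 ± 0.60 (11.54 without blue mRNA replicate 1), LARP6b (AT2G43970) by 3.75 ± 0.28, ABCF5 (AT5G64840) by 3.64 ± 0.32 and ADC1 (AT2G16500), like ADC2 an arginine decarboxylase, by 3.29 ± 0.37. F3H at 3.96 ± 0.83, FADA (AT4G27030) at 3.09 ± 0.70 and EPR1 (AT1G18330) at 3.06 ± 0.64 passed, but not without dark mRNA replicate 1 (adjusted p = 0.0548, 0.312 and 0.237). Without that library FADA was at 1.86 and EPR1 at 1.87. Efficiency fell in BT2 by 2.60 ± 0.43, in CLPP5 (AT1G02560), a subunit of the plastid Clp protease, by 2.59 ± 0.31 and in CPN20 (AT5G20720), a chloroplast co-chaperonin, by 2.48 ± 0.49. COL4 (AT5G24930) fell by 2.26 ± 0.24, TPP (AT2G30440) by 2.26 ± 0.28 and CAB2, which has near-identical copies, by 2.15 ± 0.26. UGP2 (AT5G17310) also passed, with mRNA counts of 1 and 0 in the dark and 14 and 12 in blue light. PRPL28 (AT2G33450), a plastid ribosomal protein, at -2.42 ± 0.59 lost its call without dark mRNA replicate 2 or blue mRNA replicate 1 (adjusted p = 0.0697 and 0.0806). ADS1 (AT1G06080) at -2.15 ± 0.58 lost it without dark footprint replicate 1, dark mRNA replicate 1 or blue mRNA replicate 1 (adjusted p = 0.0558, 0.0944 and 0.153), and AGD2 (AT4G33680) at -2.04 ± 0.62 lost it without each library except dark mRNA replicate 2 (adjusted p from 0.0576 to 0.167).

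Among light signalling genes, efficiency rose in 7 of 17 and fell in none (8 adjusted over the list alone), with a median of 0.88 (list adjusted p = 3.08e-06, and 0.0956 with an estimated correlation). They were SPA1, SPA3, SPA4, BBX32, RUP1, RUP2 and PIL6 (listed as PIF5), and RUP2 was the 1 of them whose mRNA was called higher. SPA4 (AT1G53090) rose by 2.47 ± 0.51 and BBX32 by 5.05 ± 0.71. SPA3 (AT3G15354) at 2.79 ± 0.59 and RUP1 (AT5G52250) at 3.02 ± 0.55 lost the call without dark mRNA replicate 1, at 1.77 and 1.95. Efficiency values without each library were not recorded for SPA4, RUP2 and PIL6. RUP2 and PIL6 passed at edgeR adjusted p of 0.0360 and 0.0487. Conserved-peptide uORF genes had a median of 1.14, with 2 of 8 risen (4 adjusted over the list alone), VTC2 and SAMDC at 1.4 ± 0.22, and SAC51 at 0.44 ± 0.76 (list adjusted p = 1.20e-04, and 0.179 with an estimated correlation). That median was 0.72 without dark mRNA replicate 2, 0.72 without blue mRNA replicate 2 and 1.91 without blue mRNA replicate 1. Of these 8 genes VTC2 and SIP3 had footprints called higher, by 4.56 and 0.49, and bZIP1, bZIP2 and XPL1 lower. GI (AT1G22770) at 1.88 ± 0.39 was the 1 clock gene of 5 that rose (3 adjusted over the list alone), in a list with a median of 1.36 (adjusted p = 0.0109, and 0.179 with an estimated correlation) whose call was lost without blue mRNA replicate 2 (adjusted p = 0.0522) and whose median was 0.77 without blue mRNA replicate 1. Flavonoid genes rose in 3 of 8 cases (3 adjusted over the list alone), F3H, 4CL3 and UGT78D1, while TT4 had a value of 0.83 ± 0.54 (list adjusted p = 0.0484, and 0.225 with an estimated correlation). That list lost its call with nuclear genes only (adjusted p = 0.0630), without blue footprint replicate 1 (0.0513) and with a trend on coding length removed (0.0569).

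The photosystem, antenna, tetrapyrrole and chloroplast-encoded lists were called lower in efficiency at the preset correlation, and none of them at the estimated correlation. In the photosystem and Rubisco list 14 of 20 genes fell and 1, PSBO1 (AT5G66570), rose (16 and 1 adjusted over the list alone), with a median of -1.15 (list adjusted p = 2.41e-23, and 0.179 with an estimated correlation). RBCS1B fell by 2.0 ± 0.24, its mRNA going from 740 ± 196 to 4796 ± 219 CPM and its footprints from 4165 ± 27 to 7446 ± 202. PSAK fell by 1.85 ± 0.24 and RCA (AT2G39730), Rubisco activase, by 1.1 ± 0.26. In the antenna 9 of 18 fell and none rose (12 fell and 1 rose adjusted over the list alone), with a median of -0.98 (list adjusted p = 9.08e-10, and 0.209 with an estimated correlation). LHCB6 (AT1G15820) fell by 1.35 ± 0.22 and LHCA3 (AT1G61520) by 1.19 ± 0.35, while LHCA1 (AT3G54890) had a value of -0.08 ± 0.44. Of the 9 falls, 6 were among the 8 LHCB1 and LHCB2 genes, whose copies can share reads, and CAB3 and CAB1, near-identical to CAB2, had values of -0.07 ± 0.23 and 0.01 ± 0.24. Outside the antenna, ELIP1 had a value of -0.36 ± 0.41, which ranged from -0.77 without dark mRNA replicate 1 to -0.0061 without dark mRNA replicate 2. Of 12 tetrapyrrole genes 4 fell and 1, GUN4, rose (4 and 2 adjusted over the list alone). PORB fell by 1.73 ± 0.24, CHLI1 (AT4G18480) by 1.65 ± 0.29, PORA by 1.02 ± 0.23 and GUN5 by 1.01 ± 0.25. PORA lost its call without blue footprint replicate 1 or 2, dark footprint replicate 1 or blue mRNA replicate 2 (adjusted p from 0.0556 to 0.0675), and GUN5 without each footprint library or blue mRNA replicate 2 (adjusted p from 0.0640 to 0.0761). The tetrapyrrole list had adjusted p = 0.0442 (0.331 with an estimated correlation) and lost the call without each library except dark mRNA replicate 2 and blue mRNA replicate 1 (adjusted p from 0.0980 to 0.265), and with the length trend removed (0.0976), and with nuclear genes only (0.0645), where its median was 0.05 against -0.04. Its median ranged from -0.47 without dark mRNA replicate 2 to 0.23 without dark mRNA replicate 1. Of 76 chloroplast-encoded genes 19 fell and 1, ATCG00020, rose by 1.76 ± 0.23 (33 fell and 1 rose adjusted over the list alone), with a median of -0.74 (list adjusted p = 6.53e-14, and 0.331 with an estimated correlation).

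In the remaining lists, efficiency rose in BETA-OHASE 2 and fell in NPQ4 among 8 photoprotection genes, rose in HSP101 and LTI78 among 9 heat shock genes, and fell in SEN1 among 13 starvation genes, with list adjusted p of 0.868, 0.171 and 0.478 and the same counts adjusted over the list alone. HSP101 lost its call without every library in turn except dark mRNA replicate 1 and blue mRNA replicate 1 (adjusted p from 0.0535 to 0.114), and SEN1 without every library except dark mRNA replicate 2 and blue mRNA replicate 2 (adjusted p from 0.0905 to 0.633). None of 9 auxin genes passed in edgeR, 1 having an unadjusted p under 0.05 (list adjusted p = 0.395). Of 14 ribosomal protein genes STV1 and SAG24 rose and P40 fell (2 and 1 adjusted over the list alone, list adjusted p = 0.868), and of 6 root markers SCR rose (1 rose and 1 fell adjusted over the list alone, list adjusted p = 0.766). These 4 calls were each lost without any 1 of the footprint libraries (adjusted p from 0.0558 to 0.117), and also without blue mRNA replicate 1 (0.300 for STV1, 0.112 for SAG24, 0.101 for P40 and 0.141 for SCR). Of 5 seed storage genes ICL rose by 1.95 ± 0.22 (1 adjusted over the list alone, list adjusted p = 0.0753). Of 25 mitochondrion-encoded genes 2, ATMG01320 and ATMG00220, fell (3 adjusted over the list alone, list adjusted p = 0.0482, and 0.366 with an estimated correlation), a list call lost without blue footprint replicate 1 or 2, dark footprint replicate 1, dark mRNA replicate 1 or blue mRNA replicate 2 (adjusted p from 0.0657 to 0.245) and with the length trend removed (0.405). ATMG01320 lost its own call without every library except dark and blue mRNA replicate 1 (adjusted p from 0.0622 to 0.222). Camera's direction opposed the sign of the median in the seed storage list.

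**Figure D2:**
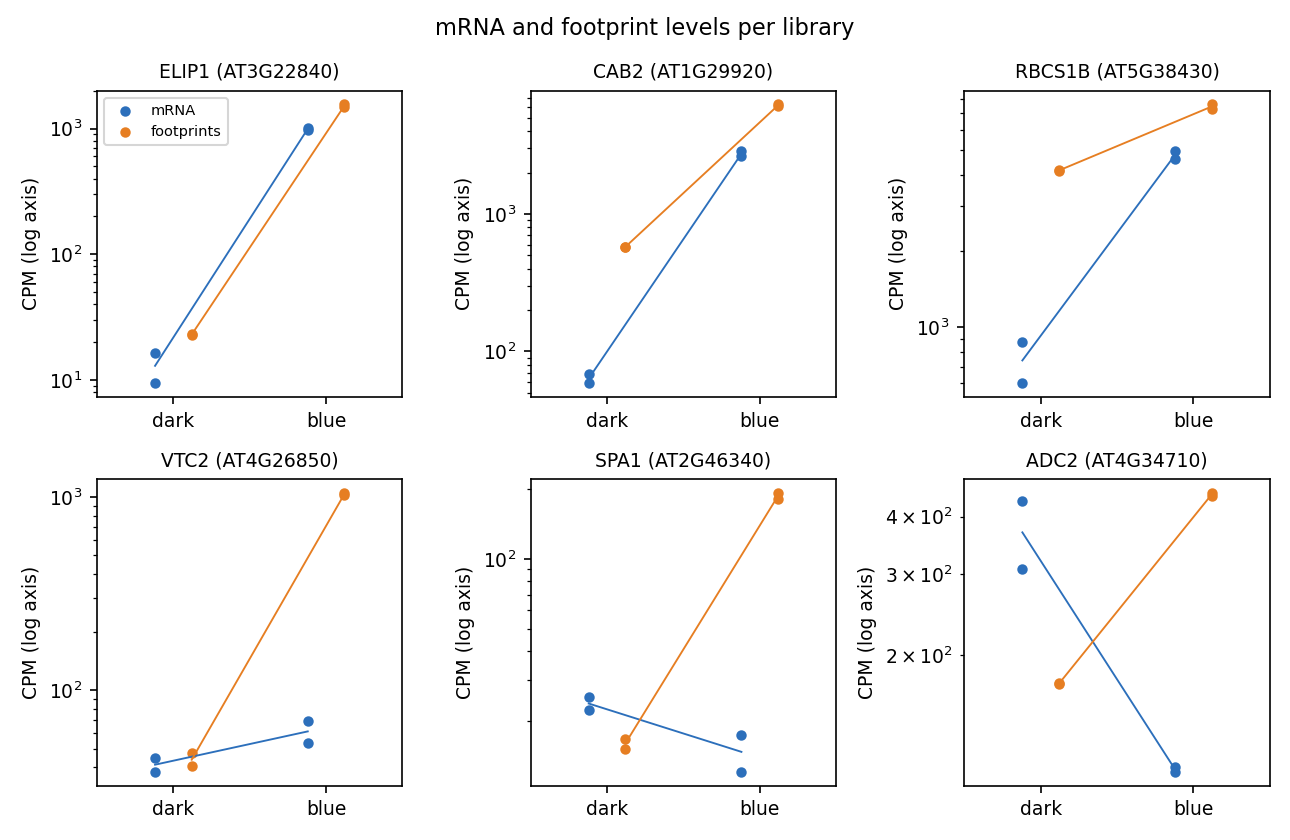
CPM on a log axis for 6 genes, with mRNA in blue and footprints in orange. Each point is a library (n = 2 per group) and lines join the group means, with VTC2 footprints going from 43.8 to 1039 CPM at mRNA means of 41.3 and 61.4 CPM.

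Efficiency changed in 625 of 6169 genes, 321 upward and 304 downward, a number that can be too high given the spread shared by both assays. The balance depended on the processing. Rises outnumbered falls by 364 to 218 when only nuclear genes were counted and by 324 to 191 when a trend on coding length was removed. Falls outnumbered rises by 326 to 299 with the DESeq2 size factors, by 363 to 305 in the DESeq2 Wald test and by 343 to 299 without dark mRNA replicate 2. Leaving out a footprint library lowered the falls more than the rises. There were 225 rises and 150 falls without blue replicate 1, and 224 and 159 without blue replicate 2. There were 208 and 137 without dark replicate 1, and 201 and 128 without dark replicate 2. Without blue mRNA replicate 2 there were 316 rises and 188 falls. Of the 321 rises, 255 had footprints called higher and mRNA not passing, and 27 had mRNA called lower. Of the 304 falls, 98 had mRNA called higher, of which 70 also had footprints called higher, and 127 had footprints called lower with mRNA not passing. The mRNA libraries enter both tests, so the overlap between mRNA and efficiency calls is not that of independent tests, and the share due to chance values in those libraries was not estimated.

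The last comparison set the changes of mRNA and footprints side by side in the 6169 genes tested in both, which share no library. Both rose in 194 genes, against 61.5 for independent lists, and both fell in 57, against 14.6. ELIP1, CAB2, TT4 and GUN5 were among those that rose in both, and XTH15, SEN1, DYL1 and DIN10 among those that fell in both. Another 1508 genes had footprints called higher and 1111 called lower with mRNA not passing, at a lower depth of mRNA. Of the 261 genes called in both assays, 251 moved in the same direction and in 10 the calls were opposite. EBF1, LARP6b and ADC2 had lower mRNA and higher footprints, ADC2 going from 370 ± 88 to 113 ± 1.9 CPM of mRNA and from 173 ± 0.13 to 447 ± 4.7 CPM of footprints, whereas PORB and TPP had higher mRNA (1.08 ± 0.24 and 1.77 ± 0.32) and lower footprints (-0.51 ± 0.06 and -0.36 ± 0.12). Across genes the log2 fold changes had a Pearson correlation of 0.413 and a Spearman correlation of 0.266, given without a p-value since genes are not independent replicates.

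**Figure D3:**
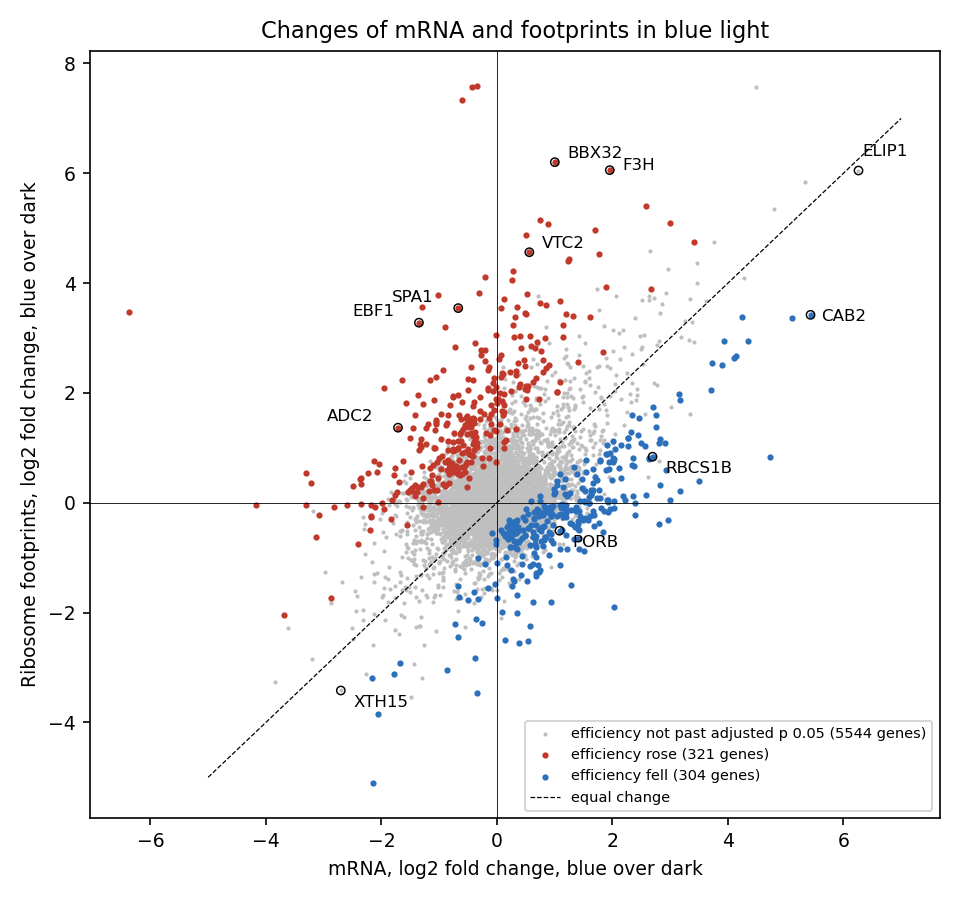
Log2 fold change of footprints against that of mRNA, blue light over darkness, for 6169 genes. Red points are the 321 genes whose efficiency rose and blue points the 304 whose efficiency fell (adjusted p under 0.05), the dashed line marks equal change, and positions of genes with few counts in a group are uncertain.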

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

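Of the tests on the pattern of opposite changes, the comparison of deviations between mRNA and footprint libraries and the test of a common shift were chosen only after the result was seen. The interaction test found 10 genes whose change in blue light differed between the assays and whose mRNA and footprints were each called in opposite directions. Efficiency rose by 4.50 in EBF1, 3.75 in LARP6b, 2.95 in ADC2, 2.36 in AT3G50370, 1.5 in HMG1, 1.5 in TIC and 1.46 in EDA10, and changed by -2.26 in TPP, -1.73 in PORB and -1.51 in ALP (log2, edgeR adjusted p from 9.87e-10 to 0.00392). In EBF1 the mRNA fell by 1.35 ± 0.35 and footprints rose by 3.28 ± 0.15, in LARP6b the mRNA fell by 1.65 ± 0.33 and footprints rose by 2.24 ± 0.12, and in ADC2 the mRNA fell by 1.71 ± 0.26 and footprints rose by 1.37 ± 0.07. In AT3G50370 the mRNA fell by 1.06 and footprints rose by 1.44. In HMG1, TIC and EDA10 the footprints rose by 0.34, 0.28 and 0.29 against falls of mRNA of -1.29, -1.36 and -1.31. In TPP, PORB and ALP the footprints changed by -0.36, -0.51 and -0.18 against rises of mRNA of 1.77, 1.08 and 1.2. Some of these calls were near the threshold, so false calls among them are possible. The edgeR adjusted p for mRNA was 0.0436 in EDA10, 0.0309 in ALP and 0.0269 in AT3G50370. For footprints it was 0.0374 in ALP and 0.0214 in TPP.

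The values argue against the choice of transcript model as the source of these opposite changes, since 5 of the 10 have a single model and with the lowest-numbered model 10 of the 10 genes kept opposite calls. They also argue against 1 shift of efficiency common to all genes, as a scaling error would give, as the source of the whole set. The reason is that 3 of the 10 genes moved against the direction of the other 7. Each lay beyond 2 standard errors, but the sign and size follow from the opposite calls that selected the genes. The split was known when the test was written, so the standard errors add no further support. Separate scaling errors in mRNA and in footprints, or a part played in 1 direction only, stay open. With nuclear genes only 10 of the 10 kept opposite signs, but that setting moved the median change of all genes by only -0.01 in mRNA and -0.00041 in footprints, less than each change it would have had to turn, so this test had a fixed outcome. Whether mRNA and footprint libraries came from the same plants is not stated, and deviations of libraries with the same number were unrelated (the higher of the 2 correlations across genes was -0.00155). Separate material can give such values, and so can independent noise in paired material, so these cannot be told apart. A response of translation to blue light also stays open and was not tested further, since it is the contrast itself.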

How the results depend on the processing

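The alternatives using the lowest-numbered transcript model, the trend on coding length and thinned footprints were chosen only after the data were seen. Of 3548 recomputed values of named genes, 3344 kept their direction and their side of the threshold, 145 lost and 44 gained a call, and 15 reversed. The values came from 235 genes and tests, some never called, recomputed from the same libraries. In 37 of these a call was ended by at least 1 alternative. Among calls shared between each alternative and the reported fit, 0 changed sign. Counts of called mRNAs ranged from 204 to 314 around 305, and counts of called footprints from 4518 to 6094 in the alternatives other than the DESeq2 Wald test and thinning. Efficiency calls ranged from 441 to 689 around 625 in the alternatives that kept all libraries.

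The DESeq2 Wald test called 3264 genes in footprints, all among the 5975, and the cause was not tested. Thinned footprints gave 1423, of which 1392 were among the 5975, from fewer counts and fewer genes tested. Leaving out each library gave 329 to 643 efficiency calls, the 4 lowest being those without a footprint library, and the cause was not tested. With an estimated correlation 0 lists were called in mRNA, 0 in footprints and 0 in efficiency, against 10, 12 and 9. Whether any list could have been called at that setting was not tested. At the level of genes the counts per list did not change with it, since it enters the list test alone. With nuclear genes only 5 lists were called in efficiency, the organelle lists being absent and the tetrapyrrole and flavonoid lists lost. The correlation of mRNA and footprint changes across genes was 0.443 with the stricter filter and 0.417 with nuclear genes only, against 0.413, over other sets of genes.

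Lists whose camera direction reversed were not called. The median of the clock list in mRNA was then 0.32 with nuclear genes only and 0.34 with the length trend removed, and from 0.27 to 0.46 without each library. Ribosomal protein genes had medians of 0.021 in mRNA and 0.14 in efficiency with the length trend removed. Without each library they ranged from -0.063 to 0.39 in mRNA and from -0.32 to 0.059 in efficiency. Light signalling in mRNA ranged from -0.43 to -0.11 without each library, although its median over all libraries was 0.07. More genes passed the filter in the fits without a library, so the tested members of a list can differ. Seed storage in footprints ranged from -1.61 to 0.20, and in efficiency photoprotection from 0.072 to 0.46 and starvation from -0.47 to 0.12.

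Single genes that reversed without a library were not called either. In mRNA the values ranged from -0.032 to 1.58 for LHY, -0.15 to 0.72 for ELF3, -1.17 to 0.25 for SHV2, -0.85 to 0.43 for LRX1, -0.13 to 0.95 for CRU3, -1.59 to 0.40 for CRA1 and -2.81 to 0.24 for SAC51. In footprints they ranged from -3.01 to 0.23 for CRU3, -1.85 to 0.11 for CRA1 and -0.040 to 0.19 for SAC51, and in efficiency from -1.17 to 2.02 for OHP2 and -0.27 to 2.88 for SAC51. The cause of these reversals was not tested.

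Deviations of libraries with the same number had correlations between -0.00296 and 0.0291 across genes. Independent noise in paired libraries can also give such values, so whether replicate numbers pair the libraries stays open. With the number as a block, 285 mRNAs, 6003 footprints and 489 efficiencies were called, and 441 efficiencies with a block within each condition. The block ended the mRNA call of ATCG00220 and the efficiency calls of AGD2, SEN1, P40, SCR and ATMG01320 (adjusted p from 0.0504 to 0.0866). It also ended the efficiency call of the tetrapyrrole list (0.0550) and added that of the seed list (0.0265). The block within each condition ended the efficiency calls of GUN5, SAG24, P40, HSP101, SCR and ATMG01320 (adjusted p from 0.0503 to 0.109). Depth and replicate spread both limit mRNA and efficiency and were not separated fully. Thinned to the nuclear counts of the shallowest mRNA library, footprints still gave 1423 calls among 6074 genes, against 305 among 7822 for mRNA. Those nuclear counts include 40001, 35737 and 5627 on AT1G40104, AT2G08986 and AT2G07981, which had no footprint counts. The thinned footprints were therefore deeper on the other nuclear genes than that mRNA library. The replicate chi-square per degree of freedom was 3.75 and 2.76 in mRNA against 1.42 and 1.61 in footprints. Efficiency changes also had a Spearman correlation of 0.172 with coding length across genes, with a median of -0.27 in the class of shortest genes and 0.15 in that of the longest. With nuclear genes only the median efficiency change over all genes moved by 0.097. The comparison of genes with an upstream ATG and its alternatives were not run.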

Other observations

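For the lower efficiency of photosystem genes, the tests on coding length and on near-identical copies were chosen only after the result was seen. The median efficiency of the nuclear photosystem and Rubisco list was 2.09 in the dark and 0.73 in blue light (log2 footprints over mRNA), against -0.05 and 0.06 over all genes. A trend on coding length is argued against as the whole source, since with it removed the median change of the list was -0.94 (SE 0.13) against -1.15. Reads shared between near-identical copies are argued against in the same way, since the 9 members with no such copy had a median of -1.13 (SE 0.09). Both SE come from resampling genes as if independent, although the estimated correlation between the genes of the list was 0.61. They leave out the spread between libraries. The list median was -1.52 without dark mRNA replicate 2 and -0.86 without dark mRNA replicate 1, and the 2 tests were not repeated without each library. A change of translation in blue light stays open and was not tested further.

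The rise of efficiency in the conserved-peptide uORF list has VTC2 as its largest member. Without VTC2 the list kept a median of 0.87 over 7 genes, with a camera p of 0.0141 (limma, 0.0375 when adjusted over the lists). With the length trend removed the list of 8 had a camera p of 3.06e-06 (9.80e-06 adjusted). At the preset correlation, neither VTC2 alone nor length is therefore likely to be the whole source. The list without both VTC2 and SAMDC was not tested, and these tests were not repeated without each library. With an estimated correlation the camera p without VTC2 was 0.225, so the call depends on the setting of the list test. Of the 7 genes other than VTC2, SAMDC alone had a called rise of the ratio or a called fall of mRNA, and the shares of mRNA and footprints in the list value were not tested. In bZIP2, SAMDC, SAC51, HB-1 and SIP3, whose fitted ratio changes were positive, the mRNA changes were -2.30, -1.42, -0.53, -1.23 and -1.14 (SAC51 from -2.81 to 0.24, HB-1 from -1.76 to -0.51 and SIP3 from -2.05 to -0.64 without each library) and the footprint changes -0.47, 0.13, 0.07, -0.24 and 0.49, while in bZIP1 and XPL1 the footprints changed by -1.41 and -0.26. Relief of inhibition by the peptide, and transcripts that start downstream of the uORF, were not tested, since counts per coding region do not separate them.

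Some loci went from near absence to clear footprint counts. AT5G42760 had 0 and 2 footprint counts in the dark and 293 and 225 in blue light, BBX16 had 0 and 0 against 24 and 20, and AT2G19650 had 0 and 0 against 26 and 27. AT3G52740, written in the light signalling list as BIC1, had 1 and 0 against 72 and 68, and PAP1, an activator of flavonoid synthesis, 0 and 1 against 56 and 46.

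Families defined by their symbol were looked at after the values were seen, and only some of those looked at are given. Of all 15788 genes tested in footprints 3304 rose and 2671 fell. Other families were mixed, with 14 rises and 7 falls among 47 MYB genes and 37 rises and 21 falls among 112 CYP genes. Of 23 XTH genes tested in footprints 16 fell and 2 rose, XTH32 by 3.61 and XTH6 by 1.72. Of 31 WRKY genes 10 fell and WRKY21 rose, by 0.64, with WRKY22 at -2.71. All 5 tested ABCF genes rose in footprints, ABCF5 by 4.06, ABCF2 by 3.5, ABCF1 by 1.37, ABCF4 by 0.37 and ABCF3 by 0.35. The DESeq2 size factors moved the median footprint change of all genes by 0.00205. That comparison cannot show a scaling error common to both methods, so it does not decide whether the smaller rises reflect scaling. Efficiency was called higher in ABCF1 at 1.68 and ABCF5 at 3.64. The chloroplast gene ATCG00020 had an mRNA change of -0.01 ± 0.18 while its footprints rose by 1.88 ± 0.10.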
